A study of Mus musculus with 36 samples.

How the data were processed

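Messenger RNA was measured in whole kidneys of 36 mice, 9 in each of 4 groups formed by genotype (control or cKOt) and treatment (PBS or STZ). Per the labels' protocols, doxycycline at 2 mg/ml was given for 2 weeks from an age of 8 weeks, and STZ at 50 mg/kg was injected daily for 5 days, 1 week later. Kidneys were collected 8 weeks after the last injection at zeitgeber time 9. Libraries were made with TruSeq Stranded mRNA reagents from 500 ng of total RNA. Each library came from a separate animal. Groups were taken from the sample titles.

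The deposited files hold, per library, the number of reads assigned to each gene, a raw count made by the authors. The submitters' processing notes name cutadapt 1.8, STAR 2.5.3a and HTSeq 0.9.1 and the GRCm38 genome. Strand and counting options and the annotation release were not given in the sources used here. The values were checked to be whole numbers at least 0, with 53715 genes in each of the 36 files and 5 further entries for reads in no gene. Of the genes, 53620 had a symbol in GENCODE M21, which was used here for symbols and coordinates, and 31610 had a read in any library. Assigned reads were 20.1 ± 1.23 M in PBS-control, 20.6 ± 1.82 M in STZ-control, 19.9 ± 1.77 M in PBS-cKOt and 19.7 ± 1.29 M in STZ-cKOt (mean ± SD, n = 9 each). Of all counted reads, between 30.9% and 42.8% per library mapped to more than 1 place and were not assigned, between 3.64% and 6.38% lay in no gene and between 0.582% and 0.738% in more than 1 gene. These shares were not shown to differ between groups (lowest adjusted p = 0.172, exact permutation tests). Over pairs of libraries of the same group, 144 in all, the chi-square per gene of replicate counts ran from 5.85 to 99.8 with a median of 19.3, so replicates varied by more than counting noise.

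Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr, which left 15637, and libraries were scaled by TMM. One mean per group was fitted to all 36 libraries (32 residual degrees of freedom) with quasi-likelihood F tests, and p was adjusted by Benjamini and Hochberg's method within each contrast, with a threshold of 0.05. The contrasts were cKOt against control in PBS mice and in STZ mice, STZ against PBS in control mice and in cKOt mice, and the interaction, the difference between the STZ effects. Each pairwise contrast compares 18 libraries. Counts per M reads (CPM) use the TMM library sizes. Standard errors of log2 fold changes come from the quasi-likelihood F statistic.

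A total of 31 gene lists and 15 marker lists were written before the data were examined, as were the contrasts, the naming rule and most of the other settings named here. A list of p53 targets was added after seeing the data and is used only in the closing section. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and adjusted over the lists of a contrast. Each was also tested with a correlation estimated per list and with fry. Members were counted by their p adjusted over all tested genes and, separately, by their p adjusted over the list alone. The text names the 7 largest rises and 7 largest falls of each pairwise contrast among genes past the threshold with a mean of at least 2 CPM and a symbol other than a predicted-gene name, and up to 10 interaction genes by adjusted p. It also names up to 4 members of a list, those with the smallest adjusted p (all members in lists of 5 or fewer), and Arntl, Pck1, G6pc, Fbp1, Slc5a1, Slc5a2, Slc2a2 and Ppargc1a.

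Other settings, also fixed in advance, were the size factors of DESeq2 in edgeR, the Wald test of DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, a filter at a mean of 1 CPM, a fit to only the 2 groups of a contrast, the replicate number as a block, and 2 surrogate variables from sva 3.50.0. Leaving out the library labelled STZ-control 2 and leaving out the 4 libraries that stood apart on the second principal component (STZ-control 7 and 8, PBS-cKOt 1 and 3) were chosen after seeing the data. These 4 also had the most negative slopes of log2 CPM, relative to each gene's mean, on log2 exon length. The slopes were −0.144 and −0.0795 in STZ-control 7 and 8 and −0.170 and −0.0753 in PBS-cKOt 1 and 3. The next lowest was −0.0605, in PBS-control 3. The cause was not tested. The replicate numbers were not treated as pairs. No library was left out of the results reported. The closing section gives the effect of each alternative, and other splits of the libraries tested whether chance groupings give as many genes.

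The gene test was tested on simulated data with the means and spreads of these libraries. It recovered 83.3%, 94.0% and 98.5% of genes changed 1.5-, 2- and 4-fold in the knockout contrast of PBS mice. Of its 197 calls 7.61% were false, above the nominal 5%. In the STZ contrast of control mice, where no change was simulated, 0 genes were called. Of 46 simulated lists of 15 genes, the 1 list shifted by 0.5 on the log2 scale was called, and 0 of the unchanged lists were. The simulated genes were independent, so the list test was not tried on correlated genes.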

Results

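The series measured messenger RNA in whole kidneys of 36 mice in a 2 by 2 design of genotype and treatment, with 9 mice in each of 4 groups. The cKOt mice carried a deletion of Bmal1 (gene symbol Arntl), the core activator of the circadian clock. The deletion was induced with doxycycline in the renal tubule of adult animals. Littermates without it, given the same doxycycline, served as controls. Mice received streptozotocin (STZ), a toxin of pancreatic beta cells that produces type 1 diabetes, or the vehicle phosphate-buffered saline (PBS). Kidneys were taken 8 weeks after the last injection at zeitgeber time 9, in hours from lights on. The groups are called PBS-control, STZ-control, PBS-cKOt and STZ-cKOt. Between 16.9 and 22.3 M reads per library were assigned to genes (median 20.1 M), and between 20482 and 22079 genes had at least 1 read. Mitochondrial genes took 16.4% ± 2.11 of assigned reads in PBS-control, 18.8% ± 3.76 in STZ-control, 14.4% ± 1.83 in PBS-cKOt and 15.8% ± 1.71 in STZ-cKOt (mean ± SD, n = 9 each). Single libraries ranged from 12.1% to 25.6%.

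The targeted gene was examined first, in every library. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, GRCm38) stood at 1.90 ± 0.405 counts per M assigned reads (CPM) in PBS-control and 3.19 ± 3.86 in STZ-control. It stood at 15.3 ± 1.47 CPM in PBS-cKOt and 14.4 ± 1.33 in STZ-cKOt (mean ± SD, n = 9 each). Its count was thus higher, not lower, in the knockout, by 3.00 ± 0.29 on the log2 scale in PBS mice (± SE; edgeR adjusted p = 1.22e-10) and by 2.16 ± 0.27 in STZ mice (adjusted p = 6.49e-08). The count covers the whole gene, with exons outside the deletion and cells outside the tubule, so it does not show the deletion itself. Only its contrast between genotypes could be set against the labels. In 1 library the contrast went against the label. The library labelled STZ-control 2 had 13.4 CPM of Arntl, where the other 8 STZ-control libraries had between 1.18 and 2.64 and the 18 knockout libraries between 12.9 and 17.4. It also had 1.95 CPM of Ciart, where the other 8 had between 18.2 and 32.5. This library was kept under its label and enters every contrast that uses STZ-control. Without it the difference of Arntl in STZ mice was 2.91.

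**Figure D1:**
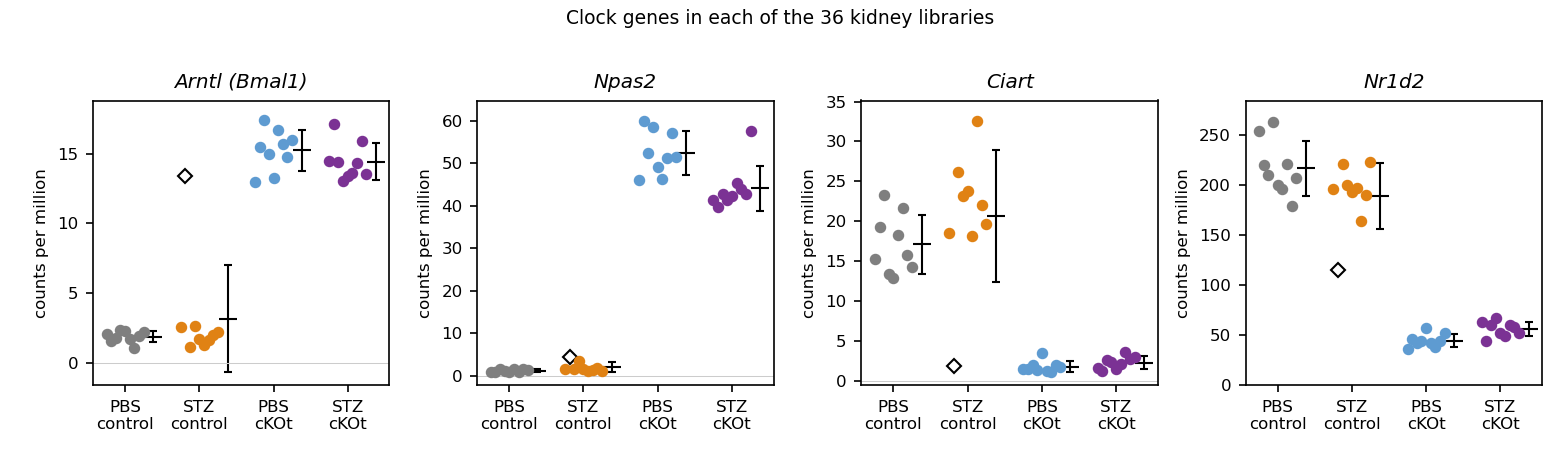
CPM of the clock genes Arntl, Npas2, Ciart and Nr1d2 in each library, 1 point per mouse, with the mean and SD of each group of 9 drawn to the right of its points. The open diamond is the library labelled STZ-control 2, which lay at 13.4 CPM for Arntl and at 1.95 CPM for Ciart, with the knockout groups rather than with the other STZ-control libraries. Its Npas2, at 4.49 CPM, lay near the other STZ-control libraries (up to 3.40) and far from STZ-cKOt (39.7 to 57.6). Its Nr1d2, at 114.5 CPM, lay between the other STZ-control and the STZ-cKOt libraries.

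Deleting Bmal1 in the tubule of PBS mice changed genes of the clock and others outside it. Npas2, a paralog of Clock that pairs with BMAL1 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236), rose 47.0-fold, from 1.11 ± 0.312 to 52.5 ± 5.11 CPM (mean ± SD, n = 9 per group; edgeR adjusted p = 5.57e-24). Ciart, a repressor of the CLOCK and BMAL1 complex (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251), fell 9.50-fold, from 17.1 ± 3.69 CPM (adjusted p = 1.11e-11). Outside the clock, the water channel gene Aqp8 (ENSMUSG00000030762, chromosome 7, 123462291 to 123468004) rose 33.1-fold. The fibrinogen chain gene Fgg (chromosome 3, 83007724 to 83015049) rose 17.3-fold, and Bhmt, an enzyme that remethylates homocysteine (chromosome 13, 93616675 to 93637961), 16.3-fold. The synaptic vesicle gene Synpr (chromosome 14, 13284780 to 13616340) fell 35.3-fold and the xenobiotic-metabolising Cyp2a5 (chromosome 7, 26835305 to 26843548) 15.2-fold.

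In all, 3661 of 15637 tested genes differed between the genotypes in PBS mice at an adjusted p under 0.05. Of these, 1707 were higher and 1954 lower in cKOt, and 194 and 201 differed by at least 2-fold. The 7 largest rises also held Fhad1 (log2 4.82 ± 0.23), the lysyl oxidase gene Loxl4 (3.98 ± 0.18) and the aldo-keto reductase gene Akr1c6 (5.64 ± 1.71, adjusted p = 0.0137). Akr1c6 was read at 76.0 to 95.8 CPM in 4 libraries and at no more than 0.935 CPM in the other 32. With DESeq2 its difference was 0.31 (adjusted p = 0.561, the highest of its settings). The 7 largest falls further held Angptl7 (−3.81 ± 0.31), Anks1b (−3.50 ± 0.27), Ctxn3 (−3.21 ± 0.37) and Ucp1, the uncoupling protein of brown fat (−3.15 ± 0.83, adjusted p = 0.00462). Ucp1 in PBS-control rested on replicate 8, at 106.7 CPM, and DESeq2 gave it −0.66 (adjusted p = 0.694, the highest of its settings). Each of the other named genes lay on 1 side of every PBS-control library in 9 of 9 cKOt libraries, except Synpr with 8 of 9.

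Of the gene lists fixed in advance, 13 were called in this contrast. All 5 clock genes with ROR/REV-ERB elements rose, with Cry1 at 2.41 ± 0.17, the bZIP repressor gene Nfil3 at 3.47 ± 0.26 and Arntl among them. The list passed camera with a median of 3.00 (adjusted p = 1.61e-12; adjusted p = 0.000834 with an estimated correlation). That median is the value of Arntl, the targeted gene, and the list was not tested without it. Of the 15 clock and E-box output genes 11 fell and 2 rose, also when adjusted over the list alone. Among them Nr1d2, which encodes REV-ERB beta, stood at −2.29 ± 0.10 and Per3 at −1.88 ± 0.14. The list median was −0.68 (adjusted p = 4.18e-08; adjusted p = 0.0927 with an estimated correlation). In the list of PAR-bZIP and xenobiotic output genes 9 of 13 fell and 0 rose (9 and 1 over the list alone). They included Por, the electron donor of the cytochromes P450 (−0.85 ± 0.07), and the carboxylesterase gene Ces1g (−2.31 ± 0.22), and the list median was −0.71 (adjusted p = 4.77e-09; adjusted p = 0.000906 with an estimated correlation). Organic ion and drug transport had 8 of 16 members lower and 0 higher, also over the list alone. The organic anion transporter gene Slc22a8 stood at −0.94 ± 0.12, the carnitine transporter gene Slc22a5 at −0.84 ± 0.08 and the list median at −0.16 (adjusted p = 0.00283; adjusted p = 0.0382 with an estimated correlation). Of the 13 lists, the ROR/REV-ERB, PAR-bZIP and organic ion lists kept their call with an estimated correlation.

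The other 9 called lists had lower medians in PBS-cKOt, and none kept its call with an estimated correlation. Androgen-responsive kidney genes had 8 of 11 members lower and 0 higher (8 and 1 over the list alone), such as Odc1, the first enzyme of polyamine synthesis (−1.34 ± 0.14). Their median was −0.71 (adjusted p = 4.39e-06; adjusted p = 0.0588 with an estimated correlation). Cholesterol synthesis had 8 of 20 lower and 1 higher, also over the list alone, with Sqle, which encodes squalene epoxidase, at −0.74 ± 0.09. Its median was −0.19 (adjusted p = 7.7e-05; adjusted p = 0.239 with an estimated correlation). Fibrosis and matrix genes had 8 of 19 lower (9 over the list alone), with Fn1, which encodes fibronectin, at −0.78 ± 0.17 (adjusted p = 0.00145; adjusted p = 0.64 with an estimated correlation). Fatty acid oxidation had 8 of 25 lower and 2 higher (11 and 2 over the list alone), with the acyl-CoA dehydrogenase gene Acadl at −0.70 ± 0.07 and the fatty acid transporter gene Cd36 at −0.70 ± 0.10. This list had a median of −0.14 (adjusted p = 0.0293; adjusted p = 0.65 with an estimated correlation). Of the 7 tested mitochondrially encoded mRNAs 3 fell (6 over the list alone), with mt-Nd2 at −0.43 ± 0.11 (adjusted p = 0.0344; adjusted p = 0.64 with an estimated correlation). This list was written with 13 members. The filter on low counts removed mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8, so the list result does not cover them. The mitochondrial share of reads was 14.4% ± 1.83 in PBS-cKOt and 16.4% ± 2.11 in PBS-control (n = 9 each). Among cell type markers, 6 of 13 for the proximal tubule fell, also over the list alone, with the dicarboxylate transporter gene Slc13a3 at −0.50 ± 0.08 (adjusted p = 0.00145; adjusted p = 0.207 with an estimated correlation). Markers of macrophages (3 of 8 lower, such as Cd74 at −0.47 ± 0.12), fibroblasts and mural cells (5 of 7) and endothelium (1 of 7, Cdh5) each had an adjusted p = 0.0435. With an estimated correlation these were adjusted p = 0.64, 0.611 and 0.64, and over each list alone 3, 5 and 5 were lower.

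Deleting Bmal1 in STZ mice moved many genes in the direction seen in PBS mice. Aqp8 rose 26.0-fold, from 1.21 ± 0.803 to 30.4 ± 7.90 CPM, and Npas2 rose 22.0-fold, from 1.99 ± 1.18 to 44.1 ± 5.29 CPM (mean ± SD, n = 9 per group). The amino acid transporter gene Slc7a12 (ENSMUSG00000039710, chromosome 3, 14480697 to 14505830) rose 16.5-fold (adjusted p = 1.17e-11). Cyp2a5 fell 45.0-fold, from 147.0 ± 54.6 to 3.25 ± 0.818 CPM. Its neighbour Cyp2a4 (ENSMUSG00000074254, chromosome 7, 26307169 to 26315088) fell 17.4-fold and Cyp4a12a (chromosome 4, 115299046 to 115332815) 10.8-fold. The largest adjusted p of these genes by edgeR was 1.86e-09, for Cyp4a12a. Fgg (log2 3.99 ± 0.27), Fhad1 (3.97 ± 0.22), Bhmt (3.76 ± 0.29) and Loxl4 (3.50 ± 0.17) completed the 7 largest rises. Synpr (−4.69 ± 0.72), Angptl7 (−3.84 ± 0.35), Anks1b (−3.36 ± 0.31) and Ciart (−3.14 ± 0.28) completed the 7 largest falls. Reads that map to more than 1 place were not counted. Cyp2a4 and Cyp2a5, and Cyp4a12a and Cyp4a12b, are near-identical pairs, so the share of reads within each pair is uncertain.

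A total of 3061 genes passed the threshold in STZ mice, 1488 higher and 1573 lower in cKOt, with 161 and 194 of them changed at least 2-fold. Without the library labelled STZ-control 2 the count was 2923. The 5 ROR/REV-ERB genes, the targeted gene Arntl included, all rose again (median 2.16, camera adjusted p = 1.78e-14; adjusted p = 0.000275 with an estimated correlation). Clock and E-box output genes again had 11 members lower and 2 higher, also over the list alone, with Nr1d2 at −1.75 ± 0.10 and Tef at −0.90 ± 0.07. Their median was −0.58 (adjusted p = 1.25e-06; adjusted p = 0.181 with an estimated correlation). PAR-bZIP and xenobiotic genes had 10 of 13 lower and 1 higher, also over the list alone, with Por at −0.78 ± 0.07 (adjusted p = 1.04e-08; adjusted p = 0.00084 with an estimated correlation). Androgen-responsive genes had 9 of 11 lower and 0 higher, also over the list alone. The acyl-CoA synthetase gene Acsm3 stood at −1.14 ± 0.17 and Odc1 at −1.15 ± 0.14 (adjusted p = 1.51e-07; adjusted p = 0.0216 with an estimated correlation). Organic ion and drug transport had 10 of 16 lower and 1 higher (11 and 3 over the list alone), with Slc22a8 at −1.20 ± 0.12 and the efflux pump gene Abcb1a at −0.86 ± 0.15. The median of the list was −0.27 (adjusted p = 0.000868; adjusted p = 0.0147 with an estimated correlation). Of the 15 lists called in STZ mice 4 kept their call with an estimated correlation, and of the 5 described here only the E-box list lost it.

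Camera also called inflammation genes and macrophage markers lower in the kidneys of STZ-cKOt than of STZ-control mice. Of 14 inflammation genes 7 fell and 0 rose (8 and 0 over the list alone), with the chemokine genes Cxcl1 at −1.34 ± 0.27 and Cxcl10 at −0.70 ± 0.12. The list median was −0.45 (adjusted p = 0.00109; adjusted p = 0.181 with an estimated correlation). Macrophage markers had 6 of 8 lower (7 over the list alone), with Csf1r at −0.36 ± 0.07 and the complement gene C1qb at −0.53 ± 0.11 (adjusted p = 0.000285; adjusted p = 0.181 with an estimated correlation). Unfolded protein response genes had 4 of 17 lower (8 over the list alone), with Herpud1 at −0.56 ± 0.08 (adjusted p = 0.00152; adjusted p = 0.233 with an estimated correlation). Proximal tubule markers had 6 of 13 lower and 0 higher (6 and 1 over the list alone), with Miox, which opens the ring of inositol, at −0.80 ± 0.11 (adjusted p = 0.00173; adjusted p = 0.181 with an estimated correlation). Fatty acid oxidation had 9 of 25 lower and 4 higher (10 and 4 over the list alone), with the thiolase gene Acaa1b at −1.07 ± 0.12 (adjusted p = 0.0141; adjusted p = 0.587 with an estimated correlation). Mitochondrially encoded mRNAs had 5 of the 7 tested members lower (6 over the list alone), with mt-Nd1 at −0.48 ± 0.11 (adjusted p = 0.00855; adjusted p = 0.474 with an estimated correlation). Their call was lost without the 4 libraries that stood apart on the second principal component (adjusted p = 0.0652), and the mitochondrial share was 15.8% ± 1.71 in STZ-cKOt and 18.8% ± 3.76 in STZ-control (n = 9 each).

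Cell cycle genes had 7 of 18 lower and 2 higher in STZ-cKOt, also over the list alone, with the cyclin D1 gene Ccnd1 at −1.33 ± 0.11 and the cyclin inhibitor gene Cdkn1a at 1.10 ± 0.11. The list had an adjusted p = 0.04 (adjusted p = 0.532 with an estimated correlation), or 0.1 without the library labelled STZ-control 2. Heat shock genes had 3 of 12 lower, such as Hsph1 at −0.53 ± 0.11 (adjusted p = 0.0298; adjusted p = 0.449 with an estimated correlation; 0.0536 without the 4 libraries). NRF2 and glutathione genes had 6 of 17 lower and 1 higher, such as the heme oxygenase gene Hmox1 at −0.99 ± 0.13. Their adjusted p was 0.0411 (adjusted p = 0.474 with an estimated correlation), or 0.073 without the library labelled STZ-control 2. Counts over the list alone were the same for both. Fibrosis and matrix genes had 2 of 19 lower, Acta2 (−0.38 ± 0.12) and Timp2 (−0.21 ± 0.08), and 0 over the list alone. Their adjusted p was likewise 0.0411 (adjusted p = 0.666 with an estimated correlation), or 0.0818 without the library labelled STZ-control 2.

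The effects of the knockout in PBS and in STZ mice, which share no library, were compared across genes, which are not independent replicates. Over 15637 genes Pearson's r was 0.75 and Spearman's rho 0.519. In both treatments 878 genes were higher and 909 lower in cKOt, against 162.4 and 196.6 that independent lists would share, and 2 genes were called in opposite directions. Ppard, a fatty-acid-sensing nuclear receptor gene (ENSMUSG00000002250, chromosome 17, 28232700 to 28301474), rose from 13.1 ± 1.64 to 114.0 ± 21.4 CPM in PBS mice. In STZ mice it rose from 13.6 ± 2.38 to 65.5 ± 15.7 CPM (mean ± SD, n = 9 each). The angiotensinogen gene Agt rose by 1.22 ± 0.09 in PBS and 0.72 ± 0.09 in STZ mice on the log2 scale, and the phosphate transporter gene Slc34a2 by 1.66 ± 0.15 and 1.62 ± 0.15. The vasopressin receptor gene Avpr1a rose by 1.52 ± 0.13 and 1.58 ± 0.12, and Slc16a1, which carries lactate and ketone bodies, by 1.86 ± 0.18 and 1.59 ± 0.18. Their lists did not pass camera in either knockout contrast. The renin-angiotensin list had adjusted p = 0.204 and 0.224, phosphate, calcium and vitamin D handling 0.229 and 0.0923, water handling 0.458 and 0.472, and ketone bodies 0.281 in STZ mice.

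**Figure D2:**
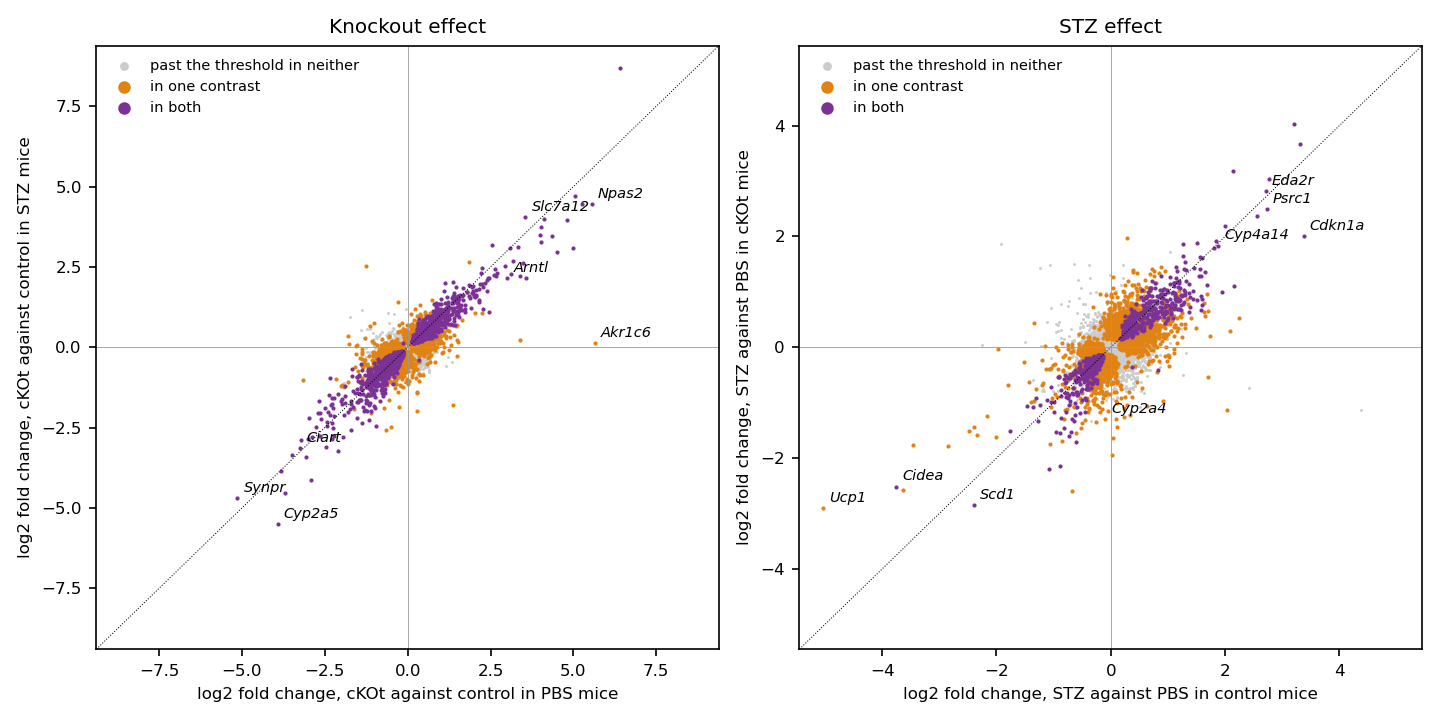
Log2 fold change of each of 15637 tested genes, for the knockout in PBS mice against STZ mice (left) and for STZ in control mice against cKOt mice (right), coloured by whether the gene passed an adjusted p of 0.05 in neither, 1 or both contrasts, with the dotted line marking equal change. In the left panel 878 genes were higher and 909 lower in both contrasts, and in the right panel 373 and 320.

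STZ in control mice raised the lists of cell cycle, tubular injury and inflammation genes. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose 10.4-fold. It went from 3.99 ± 0.828 CPM in PBS-control to 41.4 ± 8.07 in STZ-control (mean ± SD, n = 9 each; edgeR adjusted p = 2.88e-21). Psrc1, a microtubule-binding protein gene (chromosome 3, 108383839 to 108388231), rose 6.62-fold and Eda2r, a receptor of the TNF family (chromosome X, 97333840 to 97377216), 6.55-fold. Dscaml1 rose 5.90-fold and Inka2 4.01-fold, and all 5 genes lay above every PBS-control library in 9 of 9 STZ-control libraries. Scd1, the stearoyl-CoA desaturase (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), fell 5.28-fold, from 547.5 ± 344.7 to 103.7 ± 37.9 CPM, and the lipogenic regulator gene Thrsp 5.25-fold. The PBS-control values of Scd1 were highest in replicates 6, 8 and 4, as were those of Thrsp and of the fat marker Adipoq (9.92, 9.04 and 8.46 CPM). Aldh1a3 (2.09 ± 0.52, adjusted p = 0.00657) and Cyp4a14 (1.88 ± 0.63, adjusted p = 0.0434) closed the 7 largest rises. Cyp4a14 in STZ-control rested in part on replicate 9, at 323.3 CPM, where the other 8 libraries had 11.6 to 140.5. With limma voom both lay above 0.05 (adjusted p = 0.0793 and 0.1, the highest of their settings).

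Ucp1 (−5.04 ± 0.99), Cidea (−3.76 ± 0.81), Plin1 (−3.47 ± 0.79), Cidec (−2.47 ± 0.62) and Adipoq (−2.17 ± 0.73) completed the 7 largest falls, and all 5 are genes of brown or white fat. They were low in every group, with a PBS-control mean of 14.4 ± 34.7 CPM for Ucp1 and 4.05 ± 3.97 for Adipoq (mean ± SD, n = 9). The adipose tissue marker list had 3 of 4 members lower (4 over the list alone) and a median of −2.32 (adjusted p = 0.0212; adjusted p = 0.453 with an estimated correlation). The call for Adipoq (adjusted p = 0.0444) was lost without the library labelled STZ-control 2 (−2.18, adjusted p = 0.0602), and DESeq2 gave Ucp1 −2.67 (adjusted p = 0.0559). Fatty acid synthesis genes fell beside these markers. Of 12 members 7 were lower and 0 higher, also over the list alone, with the fatty acid synthase gene Fasn at −1.30 ± 0.26 and the acetyl-CoA carboxylase gene Acaca at −0.77 ± 0.16. The list median was −0.25 (adjusted p = 2.12e-05; adjusted p = 0.0637 with an estimated correlation).

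A total of 1919 genes passed the threshold for STZ in control mice, 992 higher and 927 lower, of which 146 and 39 changed at least 2-fold. With 2 surrogate variables as covariates the count was 2998, 1294 higher and 1704 lower. Cell cycle genes rose as a list, with 13 of 18 higher and 0 lower (15 and 0 over the list alone). The topoisomerase gene Top2a stood at 1.32 ± 0.18 and the cyclin gene Ccna2 at 0.90 ± 0.11, and Cdkn1a, a growth inhibitor, is counted in the list. Its median was 0.86 (adjusted p = 1.18e-19; adjusted p = 0.00478 with an estimated correlation). Tubular injury genes had 8 of 14 higher (9 over the list alone), with Lcn2, which encodes the injury marker NGAL, at 1.60 ± 0.26 and the clusterin gene Clu at 0.77 ± 0.12. The median was 0.49 (adjusted p = 8.07e-08; adjusted p = 0.0236 with an estimated correlation). Inflammation genes had 6 of 14 higher (7 over the list alone), led by the interferon-responsive Ifit1 at 1.15 ± 0.12 (adjusted p = 8.7e-08; adjusted p = 0.0236 with an estimated correlation). Proximal tubule markers had 7 of 13 lower (9 over the list alone), with Acsm2 at −0.45 ± 0.07 and the fatty acid transporter gene Slc27a2 at −0.31 ± 0.06. Here the median was −0.31 (adjusted p = 4.27e-07; adjusted p = 0.0236 with an estimated correlation). Organic ion and drug transport had 5 of 16 lower and 1 higher (6 and 1 over the list alone), with the toxin extrusion gene Slc47a1 at −0.33 ± 0.06 (adjusted p = 0.00298; adjusted p = 0.0276 with an estimated correlation). These 5 lists kept their call with an estimated correlation, of 19 called.

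Further lists were called higher in STZ-control mice by camera, none of which kept its call with an estimated correlation. Fibrosis and matrix genes had 5 of 19 higher (12 over the list alone), with the matrix protease gene Mmp2 at 0.62 ± 0.11 (adjusted p = 9.34e-07; adjusted p = 0.241 with an estimated correlation). Fibroblast and mural cell markers had 1 of 7 higher, Acta2 at 0.45 ± 0.12 (adjusted p = 0.0109; adjusted p = 0.241 with an estimated correlation). Macrophage markers had 3 of 8 higher (5 over the list alone), with C1qb at 0.54 ± 0.11 (adjusted p = 0.0101; adjusted p = 0.353 with an estimated correlation). The other 2, C1qa and C1qc, lost their calls without the library labelled STZ-control 2 (0.25, adjusted p = 0.109, and 0.29, adjusted p = 0.123). Distal convoluted tubule markers had 3 of 5 higher, also over the list alone, namely the calcium-binding Calb1 (0.81 ± 0.14) and Pvalb (0.72 ± 0.18) and the magnesium channel gene Trpm6 (0.56 ± 0.12). The median of these markers was 0.56 (adjusted p = 0.00856; adjusted p = 0.22 with an estimated correlation). Glucocorticoid-responsive genes had 4 of 12 higher (6 higher and 1 lower over the list alone), Cdkn1a again and the metallothionein gene Mt1 (0.79 ± 0.14) among them (adjusted p = 0.00121; adjusted p = 0.126 with an estimated correlation). Of 13 immediate early genes 2 rose, also over the list alone, Atf3 (1.00 ± 0.22) and Btg2 (0.82 ± 0.18) (adjusted p = 0.00677; adjusted p = 0.548 with an estimated correlation). Urothelium markers had 0 of 6 past the threshold and a median of 0.46 (adjusted p = 0.0407; adjusted p = 0.588 with an estimated correlation; 0.173 without the 4 libraries apart on the second component). Glycolysis had 2 of 18 higher and 1 lower (4 and 1 over the list alone), with Pkm at 0.30 ± 0.09 (adjusted p = 0.0409; adjusted p = 0.545 with an estimated correlation; 0.0745 without the library labelled STZ-control 2).

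Camera called 4 further lists lower in STZ-control mice, none of which kept its call with an estimated correlation. Androgen-responsive genes had 5 of 11 lower and 1 higher (6 and 1 over the list alone), with Odc1 at −0.75 ± 0.14 (adjusted p = 0.0026; adjusted p = 0.22 with an estimated correlation). Cholesterol synthesis had 4 of 20 lower, also over the list alone, with Hsd17b7 at −0.36 ± 0.08 (adjusted p = 0.000644; adjusted p = 0.241 with an estimated correlation). Ketone body genes had 4 of 7 lower, also over the list alone, with the thiolase gene Acat1 at −0.36 ± 0.06 (adjusted p = 0.0105; adjusted p = 0.0908 with an estimated correlation). Amino acid transport had 4 of 16 lower and 1 higher, also over the list alone, with Slc6a20b at −0.22 ± 0.05 (adjusted p = 0.0199; adjusted p = 0.384 with an estimated correlation; 0.173 without the 4 libraries apart on the second component).

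In cKOt mice STZ raised several of the genes it raised in controls. Eda2r rose 7.05-fold, from 1.49 ± 0.336 to 10.6 ± 2.46 CPM, and Cdkn1a 4.02-fold, from 22.1 ± 3.83 to 88.8 ± 14.5 CPM (mean ± SD, n = 9 each; edgeR adjusted p for Cdkn1a = 1.77e-15). Psrc1 rose 5.65-fold, Dscaml1 5.17-fold and Inka2 4.54-fold, and all 5 lay above every PBS-cKOt library in 9 of 9 libraries. Scd1 fell 7.23-fold, from 233.3 ± 184.5 to 32.3 ± 5.32 CPM. Its PBS-cKOt values were highest in replicates 3, 5 and 4 (544.3, 533.2 and 296.4 CPM), where the fat marker Adipoq was highest too (8.86, 7.93 and 5.01 CPM). The adipose tissue list had a median of −1.37 here, with 0 of 4 members past the threshold (adjusted p = 0.741). Inmt, an indolethylamine methyltransferase gene (ENSMUSG00000003477, chromosome 6, 55170626 to 55175043), fell 3.04-fold and the aldehyde dehydrogenase gene Aldh3b3 (chromosome 19, 3958645 to 3972103) 3.28-fold. The potassium channel gene Kcng1 fell 2.87-fold and the growth factor gene Mdk 2.75-fold. The largest rises further held Aldh1a7 (1.87 ± 0.25) and Ugt1a10 (1.98 ± 0.50), whose reads cannot be told from those of other Ugt1a genes where they share exons. The largest falls further held Cyp2a4 (−1.29 ± 0.17) and Cidea (−2.51 ± 0.83, adjusted p = 0.0413; −1.97 and adjusted p = 0.312 with limma voom, the highest of its settings).

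For STZ in cKOt mice 1819 genes passed the threshold, 939 higher and 880 lower, of which 90 and 61 changed at least 2-fold. Camera called 15 lists, of which 0 kept an adjusted p under 0.05 with an estimated correlation, while fry called 13 lists. Cell cycle genes had 9 of 18 higher (14 over the list alone), with the proliferation marker gene Mki67 at 0.99 ± 0.16 and Top2a at 1.20 ± 0.18. The list median was 0.61 (adjusted p = 1.06e-10; adjusted p = 0.0554 with an estimated correlation). Fibrosis and matrix genes had 12 of 19 higher (16 over the list alone), with Fn1 at 0.98 ± 0.17, Mmp2 at 0.79 ± 0.11 and the collagen gene Col3a1 at 0.68 ± 0.15. Their median was 0.44 (adjusted p = 1.06e-10; adjusted p = 0.102 with an estimated correlation). Fibroblast and mural cell markers had 4 of 7 higher, also over the list alone, such as Pdgfra at 0.46 ± 0.12 (adjusted p = 0.000462; adjusted p = 0.102 with an estimated correlation). Inflammation genes had 6 of 14 higher (9 over the list alone), with the complement gene C3 at 1.07 ± 0.27 (adjusted p = 1.11e-05; adjusted p = 0.0585 with an estimated correlation). Tubular injury genes had 7 of 14 higher, also over the list alone, with the osteopontin gene Spp1 at 0.71 ± 0.10 (adjusted p = 0.000444; adjusted p = 0.112 with an estimated correlation). Proximal tubule markers had 8 of 13 lower (9 over the list alone), with Miox at −0.75 ± 0.11 and Slc7a13 at −0.73 ± 0.12 (adjusted p = 9.4e-07; adjusted p = 0.0554 with an estimated correlation). Distal convoluted tubule markers had 3 of 5 higher, also over the list alone, with Calb1 at 0.84 ± 0.14 (adjusted p = 0.00185; adjusted p = 0.102 with an estimated correlation). Endothelial markers had 3 of 7 higher, also over the list alone, with Cdh5 at 0.43 ± 0.12 (adjusted p = 0.00412; adjusted p = 0.464 with an estimated correlation). Podocyte markers had 1 of 6 higher, Podxl at 0.35 ± 0.12 (5 over the list alone; list adjusted p = 0.00234; adjusted p = 0.257 with an estimated correlation). Podxl itself (adjusted p = 0.0498) lost its call without the library labelled STZ-control 2 (adjusted p = 0.0541), which enters this contrast through the shared estimate of spread.

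Lists called lower after STZ in cKOt mice by camera, none of them with an estimated correlation, included fatty acid synthesis, androgen-responsive genes and organic ion and drug transport. Fatty acid synthesis had 7 of 12 lower (8 lower and 1 higher over the list alone), with the carbohydrate-response factor gene Mlxipl at −0.35 ± 0.09 (adjusted p = 0.000444; adjusted p = 0.102 with an estimated correlation). Androgen-responsive genes had 6 of 11 lower and 1 higher (7 and 1 over the list alone), with the kidney androgen-regulated gene Kap at −0.71 ± 0.16 (adjusted p = 0.000444; adjusted p = 0.102 with an estimated correlation). Organic ion and drug transport had 6 of 16 lower and 1 higher (8 and 1 over the list alone), with Slc22a8 at −0.68 ± 0.12 (adjusted p = 0.00329; adjusted p = 0.0554 with an estimated correlation). Ketone body genes had 2 of 7 lower, also over the list alone, Bdh1 (−0.59 ± 0.08) and Acat1 (−0.42 ± 0.06) (adjusted p = 0.00744; adjusted p = 0.102 with an estimated correlation). In 2 further lists called by camera more of the members past the threshold were higher than lower. Glucocorticoid-responsive genes had 2 of 12 higher, Cdkn1a and the kinase gene Sgk1 (0.70 ± 0.15), and 1 lower, Errfi1 (−0.38 ± 0.12). Over the list alone 6 were higher and 1 lower (adjusted p = 0.00138; adjusted p = 0.102 with an estimated correlation). Glycolysis had 3 of 18 higher and 1 lower, also over the list alone, with Eno1 at 0.37 ± 0.10 (adjusted p = 0.0309; adjusted p = 0.521 with an estimated correlation). The STZ effects in the 2 genotypes, which share no library, had a Pearson's r of 0.535 and a Spearman's rho of 0.374 over 15637 genes, which are not independent replicates. In both genotypes 373 genes were higher and 320 lower, against 59.6 and 52.2 that independent lists would share, and 2 genes were called in opposite directions.

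**Figure D3:**
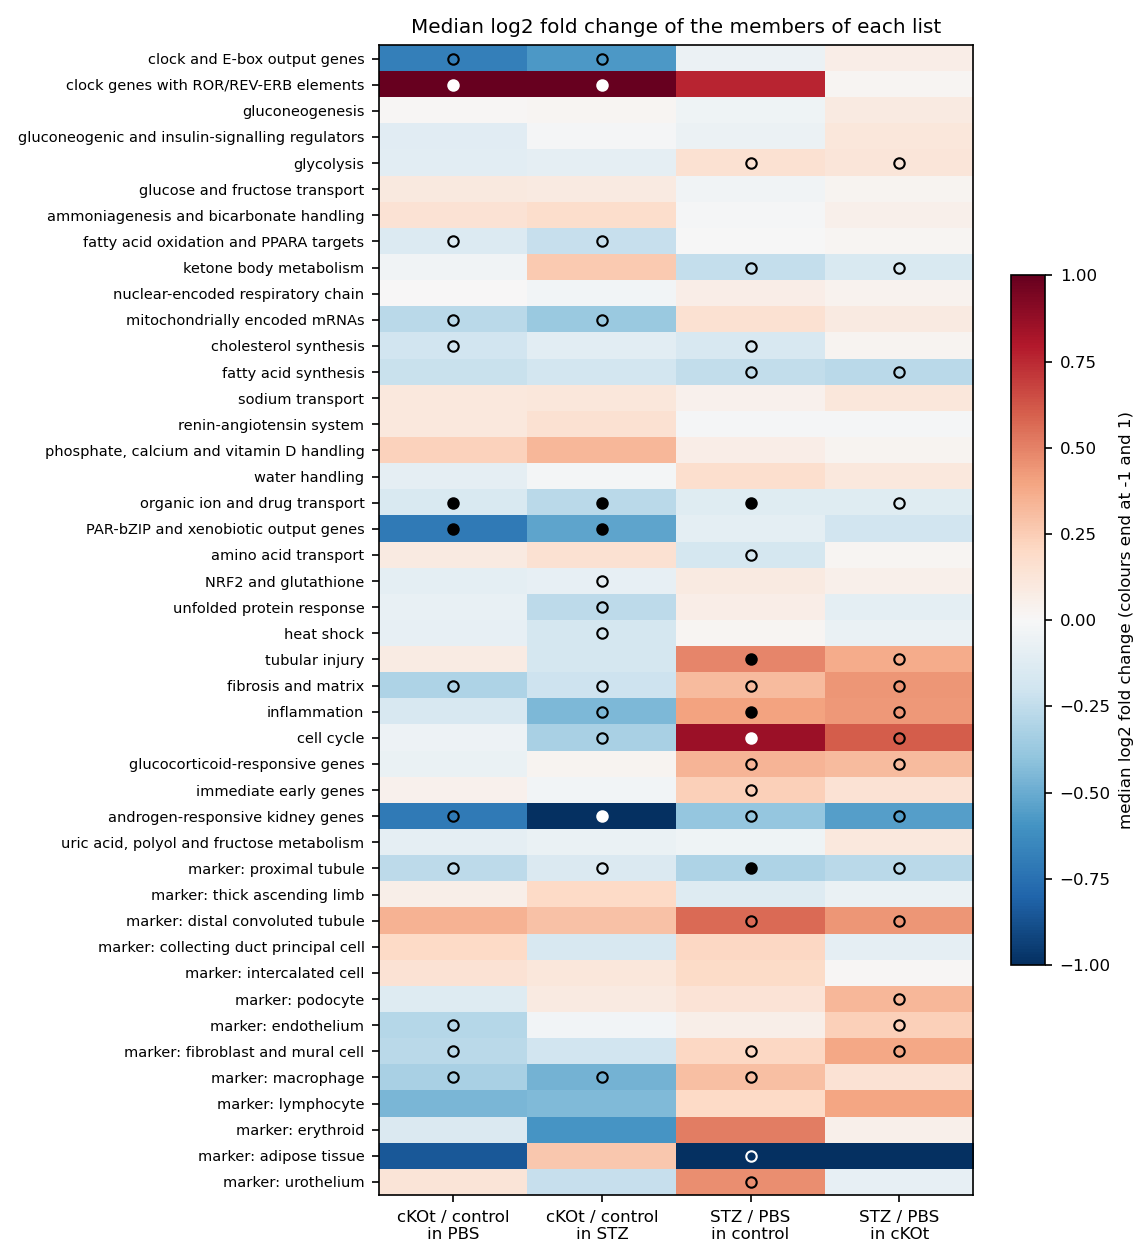
Median log2 fold change of the tested members of each of 44 gene and marker lists in the 4 pairwise contrasts, with colours ending at −1 and 1. An open circle marks an adjusted p under 0.05 by camera and a filled circle a call kept with an estimated correlation. Camera called 13, 15, 19 and 15 lists from left to right, of which 3, 4, 5 and 0 were kept.

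The series title names renal gluconeogenesis, and its genes were examined singly and as a list. G6pc, the catalytic subunit of glucose-6-phosphatase (ENSMUSG00000078650, chromosome 11, 101367561 to 101377903), was 1.84-fold higher in STZ-cKOt than in STZ-control. It stood at 601.8 ± 87.5 against 327.3 ± 71.7 CPM (mean ± SD, n = 9 each; edgeR adjusted p = 4.21e-07), and all 9 cKOt libraries lay above every STZ-control library. In PBS mice it was 1.27-fold higher in cKOt, with 619.0 ± 101.9 against 487.8 ± 89.7 CPM (adjusted p = 0.0325). After STZ it fell in control mice (−0.58 ± 0.12, adjusted p = 0.0012) and stood at −0.04 ± 0.12 in cKOt mice (adjusted p = 0.883). The interaction that compares these effects did not pass (0.54 ± 0.17, adjusted p = 0.332). Pck1, the cytosolic phosphoenolpyruvate carboxykinase (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), was 1.35-fold higher in STZ-cKOt than in STZ-control (0.43 ± 0.14, adjusted p = 0.0241). The call was lost without the 4 libraries that stood apart on the second principal component (0.38, adjusted p = 0.0692, the highest of its settings). In PBS mice Pck1 stood at 0.07 ± 0.14 (adjusted p = 0.745; interaction 0.36 ± 0.20, adjusted p = 0.431). Fbp1, the renal fructose-1,6-bisphosphatase (chromosome 13, 62864753 to 62888282), fell in PBS-cKOt (−0.24 ± 0.08, adjusted p = 0.022), with adjusted p = 0.129 with 2 surrogate variables, the highest of its settings. In STZ mice it stood at 0.06 ± 0.08 (adjusted p = 0.671; interaction 0.29 ± 0.11, adjusted p = 0.364).

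As a whole the gluconeogenesis list did not pass camera in any contrast with all 36 libraries. Without the 4 libraries apart on the second component, a setting chosen after seeing the data, it passed upward for STZ in cKOt mice (adjusted p = 0.013) and for the interaction (adjusted p = 0.00197). With all libraries and an estimated correlation these were adjusted p = 0.731 and 0.779. In PBS mice the knockout had 2 of its 14 members higher and 4 lower, also over the list alone, with the glucose-6-phosphate transporter gene Slc37a4 at −0.33 ± 0.07 and Fbp2 at 0.47 ± 0.12. The median of 0.01 differed in sign from the mean and the test (adjusted p = 0.55). In STZ mice the knockout had 4 higher and 2 lower, also over the list alone, with the lactate dehydrogenase gene Ldhb at −0.22 ± 0.06 (adjusted p = 0.472). STZ had 2 members higher and 1 lower in control mice (adjusted p = 0.8) and 1 higher and 0 lower in cKOt mice (adjusted p = 0.153), with the same counts over the list alone.

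Glucose transporter genes moved singly. Slc2a2, which encodes the basolateral transporter GLUT2 (ENSMUSG00000027690, chromosome 3, 28697903 to 28731359), was lower in PBS-cKOt than in PBS-control, with 157.0 ± 31.9 against 233.2 ± 30.9 CPM (mean ± SD, n = 9 each; adjusted p = 0.00088). After STZ it rose in cKOt mice (0.51 ± 0.13, adjusted p = 0.00619) and stood at −0.12 ± 0.13 in controls (adjusted p = 0.586). Its interaction did not pass (0.63 ± 0.18, adjusted p = 0.252). The sodium-glucose cotransporter genes Slc5a1 and Slc5a2 did not pass in any contrast (lowest adjusted p 0.439 and 0.352). Their relative Slc5a9 rose in cKOt (0.37 ± 0.05 in PBS and 0.36 ± 0.05 in STZ mice), and the fructose transporter gene Slc2a5 fell (−0.97 ± 0.11 and −0.68 ± 0.11). The glutamate dehydrogenase gene Glud1 rose in cKOt by 0.31 ± 0.09 in PBS and 0.76 ± 0.09 in STZ mice (interaction 0.45 ± 0.12, adjusted p = 0.204). The coactivator gene Ppargc1a was 0.27 ± 0.09 higher in STZ-cKOt than in STZ-control (adjusted p = 0.0229; interaction 0.28 ± 0.12, adjusted p = 0.373). Without the 4 libraries apart on the second component Ppargc1a stood at 0.20 (adjusted p = 0.06).

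**Figure D4:**
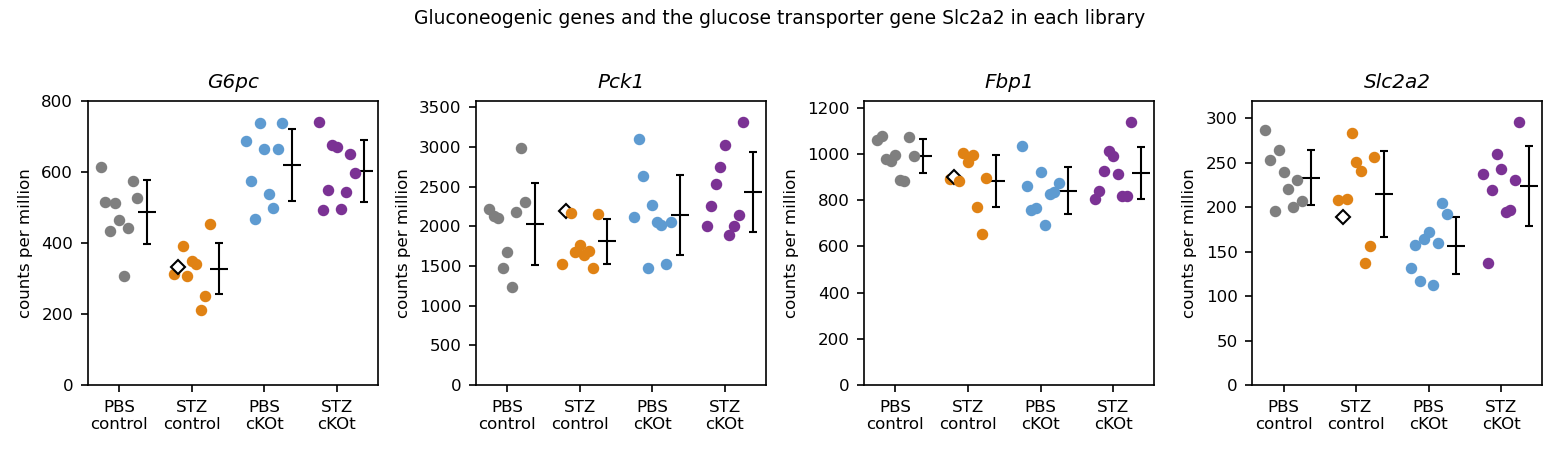
CPM of G6pc, Pck1, Fbp1 and the glucose transporter gene Slc2a2 in each library, 1 point per mouse, with the mean and SD of each group of 9 drawn to the right of its points and an open diamond for the library labelled STZ-control 2. The STZ-cKOt mean of G6pc, 601.8 CPM, lies above the STZ-control mean of 327.3 CPM.

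Of the 44 lists with at least 3 tested members, 15 passed camera in none of the 4 pairwise contrasts (lowest adjusted p 0.0923, medians from −0.59 to 0.51), and most of them still held genes that changed. In the ammoniagenesis list the knockout raised 3 of 14 members and lowered 2 in PBS mice (6 and 3 over the list alone), and the sodium-proton exchanger gene Slc9a3 fell by 0.55 on the log2 scale (adjusted p = 0.488 for the list). In STZ mice it raised 6, and lowered 3 (7 and 3 over the list alone; adjusted p = 0.188). The carbonic anhydrase gene Car2 was among the 6, at 0.43 ± 0.07 against 0.06 ± 0.07 in PBS mice (interaction 0.38 ± 0.10, adjusted p = 0.228). Sodium transport had 2 of 18 higher and 3 lower in PBS-cKOt, also over the list alone (adjusted p = 0.458), and 4 higher and 1 lower in STZ-cKOt (5 and 3 over the list alone; adjusted p = 0.229), with Sgk1 at 0.86 ± 0.15 and 0.91 ± 0.15. Sord, which makes fructose from sorbitol, was the 1 member of 6 called in the polyol list in PBS-cKOt (−0.47 ± 0.05; list adjusted p = 0.339). Respiratory chain genes encoded in the nucleus had 0 of 31 higher and 1 lower in PBS-cKOt (adjusted p = 0.688). Without the 4 libraries apart on the second component this nuclear-encoded list passed downward in PBS-cKOt (adjusted p = 0.0402) and upward for STZ in cKOt mice (adjusted p = 7.04e-05) and for the interaction (adjusted p = 7.66e-07). With all libraries and an estimated correlation these were adjusted p = 0.906, 0.832 and 0.978. Glucose and fructose transport had 3 of 15 higher and 2 lower in PBS-cKOt and 6 higher and 1 lower in STZ-cKOt, also over the list alone (adjusted p = 0.55 and 0.125). Markers of the thick ascending limb, principal cells, intercalated cells, lymphocytes and red cells did not pass either (lowest adjusted p 0.163, 0.261, 0.113, 0.143 and 0.281). The adrenal and skeletal muscle lists had 1 tested member each, Star and Mylpf, and neither gene passed in any contrast.

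The interaction asked whether the effect of STZ differed between the genotypes. By edgeR 7 genes passed an adjusted p of 0.05, all with a lower STZ effect in cKOt. Cdkn1a rose less on the log2 scale in cKOt, where it was already higher without STZ (interaction −1.37 ± 0.17, SE, adjusted p = 1.93e-05). Its mean in STZ-cKOt, 88.8 CPM, was nevertheless the highest of the 4 groups. The neighbouring apolipoprotein genes Apoc3 (ENSMUSG00000032081, chromosome 9, 46232933 to 46235636; −1.24 ± 0.21, adjusted p = 0.00405) and Apoa4 (chromosome 9, 46240696 to 46243459; −1.15 ± 0.21, adjusted p = 0.0105) parted between the genotypes. After STZ Apoc3 went from 3.71 ± 0.454 to 6.65 ± 2.07 CPM in control and from 9.16 ± 2.24 to 6.86 ± 1.44 CPM in cKOt (mean ± SD, n = 9 each). Apoa4 went from 6.14 ± 1.36 to 7.37 ± 1.88 CPM in control and from 7.73 ± 1.32 to 4.15 ± 1.07 CPM in cKOt. Ppard went from 13.1 ± 1.64 to 13.6 ± 2.38 CPM in control and from 114.0 ± 21.4 to 65.5 ± 15.7 CPM in cKOt (−0.86 ± 0.17, adjusted p = 0.0388). The replication licensing gene Mcm2 had −0.41 ± 0.08 (adjusted p = 0.0388). The pair Cyp2a4 (−1.20 ± 0.23, adjusted p = 0.0233) and Cyp2a5 (−1.57 ± 0.32, adjusted p = 0.0388), between which reads are uncertain, completed the 7.

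Interaction calls were the least firm. Without the library labelled STZ-control 2, Ppard (−0.81, adjusted p = 0.0799) and Mcm2 (−0.39, adjusted p = 0.0811) no longer passed. Without the 4 libraries apart on the second component Apoa4, Cyp2a4, Cyp2a5 and Mcm2 did not (adjusted p = 0.061, 0.113, 0.18 and 0.0829). DESeq2 called 20 genes (3 higher and 17 lower), limma voom 15 (0 and 15) and edgeR with 2 surrogate variables 29 (14 and 15). The single direction of the 7 genes was thus not kept in every setting. In the reported fit 1944 genes had an unadjusted p under 0.05. Camera called 5 lists, and all 5 had an adjusted p = 0.779 with an estimated correlation. Cholesterol synthesis had a median of 0.23 (adjusted p = 0.00015) and cell cycle genes −0.28 (adjusted p = 0.00114). Gluconeogenic and insulin-signalling regulators had 0.12 (adjusted p = 0.0359), endothelial markers 0.26 (adjusted p = 0.0359) and clock and E-box output genes 0.15 (adjusted p = 0.0382). Without the library labelled STZ-control 2 these 3 had adjusted p = 0.0747, 0.0504 and 0.227. Of the members Mcm2 and Cdkn1a passed, both in the cell cycle list (3 over the list alone), and over the list alone 2 cholesterol synthesis genes and 1 clock gene passed as well.

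**Figure D5:**
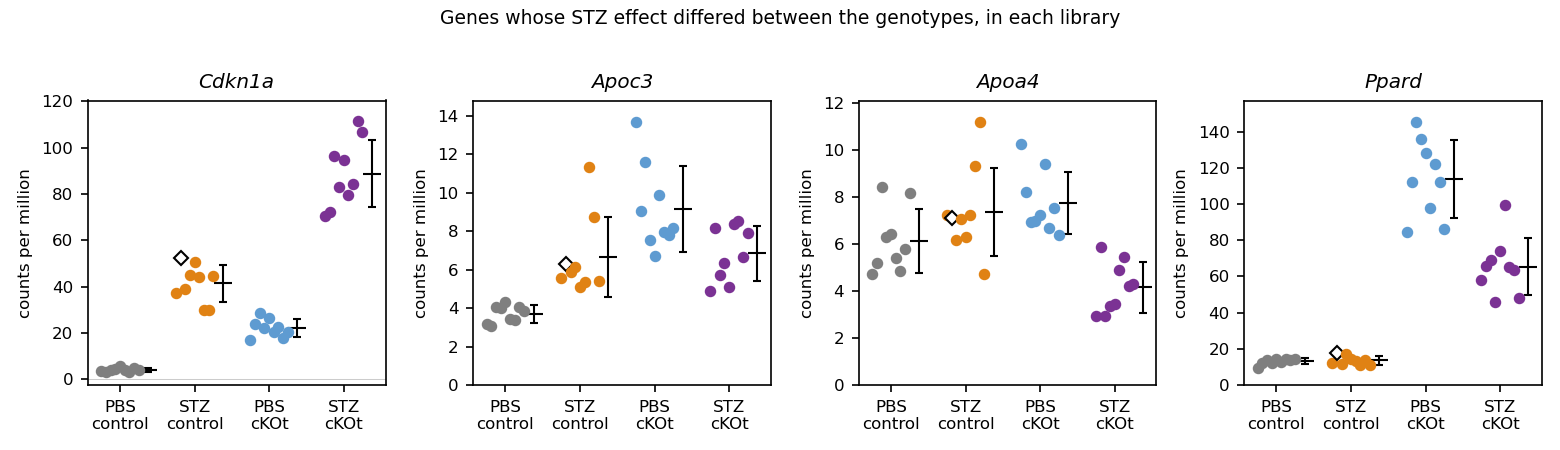
CPM of Cdkn1a, Apoc3, Apoa4 and Ppard in each library, 1 point per mouse, with the mean and SD of each group of 9 drawn to the right of its points and an open diamond for the library labelled STZ-control 2. Cdkn1a rose from 3.99 to 41.4 CPM after STZ in control and from 22.1 to 88.8 CPM in cKOt.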

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

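The tests on the library labelled STZ-control 2 and the comparison of distal with thick limb markers were chosen only after the result was seen, as was the list of p53 targets, while the other tests of this part were set before. In each group of 9 libraries the 48 named genes and 5 library measures were searched for a single library far from the other 8, by the gap to its neighbour over the range of the group. Of 212 groups 32 passed Dixon's 95% critical value, where chance flags about 1 in 20 groups, or 10.6 here, and 2 of the 32 were in the library labelled STZ-control 2. By this search mitochondrial share was high in PBS-control 3 (21.5% against 14.6 to 17.4 in the other 8), PBS-cKOt 3 (18.4% against 12.1 to 15.3) and STZ-cKOt 7 (19.9% against 14.2 to 16.8). Reads mapping to more than 1 place were at 37.8% in PBS-control 3 (32.9 to 35.2 in the others). A search for a single library can miss 2 that lie together. The highest mitochondrial shares of all were in STZ-control 7 (25.6%) and STZ-control 8 (24.7%), against 15.3% to 19.1% in the rest of that group. These 2 libraries also had the most reads mapping to more than 1 place (42.8% and 41.2%).

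Among genes, Akr1c6 stood far above the rest of the group in STZ-control 7 (76.01 CPM) and STZ-cKOt 1 (78.97). Fat genes were high in single libraries, Ucp1 in PBS-control 8 (106.7), STZ-control 1 (3.248) and STZ-cKOt 7 (0.9062), and Cidea (2.797) and Plin1 (1.714) in STZ-control 1. Cyp4a14 was high in STZ-control 9 (323.3), PBS-cKOt 8 (168.2) and STZ-cKOt 9 (894.4), and Ugt1a10 in PBS-cKOt 8 (62.91) and STZ-cKOt 9 (171.7), while Ugt1a10 was low in PBS-control 7 (1.19). Clock genes stood apart in the library labelled STZ-control 2 (Arntl 13.37, Ciart 1.949), in PBS-cKOt 5 (Ciart 3.482) and in STZ-cKOt 9 (Npas2 57.59). Fgg was high in PBS-control 9 (15.05) and STZ-control 5 (18.96), Bhmt (67.24) and Inmt (692.3) in PBS-cKOt 1, Cyp2a5 in PBS-cKOt 5 (13.88) and Fhad1 (9.053) and Eda2r (2.296) in PBS-cKOt 6. Slc5a1 was high in PBS-cKOt 8 (88.55), Slc7a12 in STZ-cKOt 1 (87.76) and Anks1b in PBS-control 1 (10.51), where Ppard was low (9.338).

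The STZ effect differed between the genotypes, by the interaction test, for Cdkn1a (log2 −1.366), Apoc3 (−1.242), Cyp2a4 (−1.198), Apoa4 (−1.15), Cyp2a5 (−1.566), Ppard (−0.857) and Mcm2 (−0.408). By camera it differed for cholesterol synthesis (adjusted p = 0.00015), the cell cycle (adjusted p = 0.00114), gluconeogenic and insulin-signalling regulators (adjusted p = 0.0359), endothelial markers (adjusted p = 0.0359) and clock and E-box output genes (adjusted p = 0.0382), each with an adjusted p = 0.779 once the correlation was estimated per list.

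In the library labelled STZ-control 2, 17 of 20 clock-list genes lay outside the range of the other 8 STZ-control libraries on the side of the knockout, where no other library had more than 6. On a scale from 0 (the other STZ-control libraries) to 1 (STZ-cKOt), its clock genes had a median position of 0.71. Its 211 knockout-responsive genes outside the lists had 0.083, within the range of the other 8 (−0.1 to 0.149), which argues against a knockout kidney under a control label and, since mixed RNA would move both sets alike, against knockout RNA mixed into a control library. Cry2 moved away from the knockout, at 20.9 CPM against 24.8 to 33.5 in the other 8 and 35.0 to 48.2 in STZ-cKOt. The 17 genes may reflect another clock phase in that mouse at sampling, which remains a hypothesis because time of day was not varied.

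Targets of p53 rose after STZ in both genotypes, with Eda2r, Psrc1 and Cdkn1a among the largest rises. In 29 tested targets not seen among the top genes 16 were higher and 0 lower in control mice and 10 and 1 in cKOt mice, with medians of 0.25 and 0.192 (p = 6.29e-07 and 2.28e-05 by limma camera, correlation estimated). Over all 40 targets, 11 of them picked from the top genes, the median in cKOt mice was 0.35. It was 0.321 with a cell cycle score as a covariate and 0.331 with the second component and mitochondrial share. In control mice it kept more. For this mixed list that argues against more cycling cells or RNA quality as the whole cause. The 29 targets alone were not tested with these covariates. Cdkn1a is also in the cell cycle and glucocorticoid lists. Activation of p53 may be part of the response to STZ, through diabetes or through a direct effect of the toxin, which the design cannot separate.

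By camera proximal tubule markers were lower after STZ and matrix, injury and distal convoluted tubule lists higher, but with an estimated correlation only the proximal and injury lists in control mice kept their call (adjusted p = 0.0236 each), while matrix (adjusted p = 0.241 and 0.102 in control and cKOt mice), distal convoluted tubule (0.22 and 0.102) and, in cKOt mice, proximal tubule (0.0554) and injury (0.112) did not. A lower share of proximal tubule RNA would raise the markers of every other segment alike. The shift of distal convoluted tubule markers exceeded that of thick ascending limb markers by 0.521 in control and 0.55 in cKOt mice. In each, 9 of 9 STZ libraries lay above the PBS mean (exact permutation p = 4.11e-05, the smallest the permutations can give). This argues against a lower proximal share as the whole cause of the distal rise. It cannot tell why proximal markers fell, since such a share cancels in the difference. Thick ascending limb markers themselves did not rise (−0.107 in control and −0.136 in cKOt mice). With the second component and mitochondrial share as covariates the proximal list kept a median of −0.217 in control mice (−0.31 without) and −0.27 in cKOt mice, which argues against RNA quality as the whole cause. A change of expression within proximal and distal cells could remain, and was not tested.

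Other splits of the libraries were drawn, 100 per contrast with the real one included. For the knockout in PBS mice 1 of 100 splits, the real one, gave 3661 genes or more (highest other 701), in STZ mice 1 gave 3061 (2438). For STZ in control mice 1 gave 1919 (436) and in cKOt mice 1 gave 1819 (47). These draws argue against chance for these counts, but 100 splits cannot show a share below 1 in 100. For the interaction 3 of 100 splits, the real one included, gave 7 genes or more. These splits shuffled STZ and PBS within each genotype, which also removes the STZ effect common to both genotypes. They therefore cannot decide whether chance gives the interaction count. Of the other splits 1 gave 1039, which points to a structure of the samples. That split had the largest difference on the second principal component of all splits drawn (35.2, against 22.8 for the real groups), but the split next in size, at 28.6, gave 0 genes. For the pairwise contrasts the highest other splits kept 14 of 18 libraries together as in the real groups (16 for STZ in control mice), so their counts may carry part of the real contrast. Overlap alone does not set the count. For the knockout in STZ mice the other splits that kept 14 gave 84, 26 and 0 genes, and in PBS mice from 0 to 430. The split with 2438 genes kept 14 and had 21.6 on this component, and one with 22.0 that kept 12 gave 0.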

How the results depend on the processing

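The 2 settings that leave out libraries were chosen after seeing the data, and the other settings before. Counts of changed genes stayed within 1.5 times the reported count in every setting run, with these exceptions, of which the cause was not tested. With 2 surrogate variables STZ in control mice changed 2998 genes (1919 as reported) and the interaction 29 (7 as reported). The interaction gave 20 genes with the Wald test of DESeq2 and 15 with limma voom, of which 7 and 6 were among the 7. With the replicate block, which treats equal numbers as paired, it gave 5, although the numbers did not pair the mice: over 54 same-number pairs the median r was 0.0225, against 0.005 for different numbers. Elsewhere the knockout counts ran from 3119 to 4314 in PBS and from 2648 to 3620 in STZ mice, and the STZ counts from 1421 to 2079 in control and from 1414 to 2689 in cKOt mice.

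The scaling by DESeq2 left 897 values of single genes on the same side of the threshold, with 4 weaker and 1 stronger. Others (weaker and stronger) were no filter 47 and 0, the filter at 1 CPM 1 and 4, limma voom 31 and 32, the 2-group fit 30 and 12, surrogate variables 22 and 35, the replicate block 17 and 14 and the DESeq2 Wald test 6 and 12. Leaving out the 4 libraries left 819 the same, 60 weaker and 23 stronger, and leaving out the library labelled STZ-control 2 left 883 the same, 15 weaker and 4 stronger. Of 220 list values, camera called 13 and 15 for the knockout in PBS and STZ mice. It called 19 and 15 for STZ in control and cKOt mice and 5 for the interaction. With an estimated correlation only 3, 4, 5, 0 and 0 of these calls were kept, so 55 were lost. With fry 12 values became weaker and 18 stronger. Without the 4 libraries the interaction of mitochondrially encoded mRNAs changed direction and passed (adjusted p = 0.0266; adjusted p = 0.978 with all libraries and an estimated correlation), and other lists that changed direction passed in neither setting. Without them 16 further list values were called that had not been, gluconeogenesis and the respiratory chain in STZ-treated cKOt mice and in the interaction among them. A sex covariate was not run, since every mouse expressed Y-linked genes and Xist stayed at or under 0.444 CPM, and a fit to only the 2 groups of a contrast does not exist for the interaction. Whole-gene counts do not resolve exons, and 30.9% to 42.8% of reads were not counted for mapping to more than 1 place, which limits copies such as Cyp2a4 and Cyp2a5.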

Other observations

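The list of p53 targets and the genes of this part were chosen only after the result was seen. Trp53cor1, a long non-coding RNA induced by p53, rose by 2.77 after STZ in control and by 3.03 in cKOt mice on the log2 scale. Its counts were low, at no more than 0.217 CPM in any PBS library and 0.284 to 1.41 CPM in the STZ libraries. This is under the limit of 2 CPM used for the named genes. Phlda3, a repressor of AKT signalling, rose by 1.45 and 1.43, the pro-apoptotic Bbc3 by 0.93 and 1.05, Mdm2, the ligase that degrades p53, by 0.43 and 0.41, and the stress cytokine gene Gdf15 by 1.37 and 0.64. Over all 40 tested p53 targets, 11 of them picked from the top genes, 27 were higher in control and 21 in cKOt mice. Their medians were 0.34 and 0.35, and the interaction of the list did not pass (p = 0.359 by limma camera with an estimated correlation).

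Single genes outside those named so far are given here as values, with no theme tested. After STZ the epoxide hydrolase gene Ephx1 rose by 1.10 ± 0.10 in control and 1.17 ± 0.10 in cKOt mice, and the betaine transporter gene Slc6a12 by 1.04 ± 0.25 and 1.27 ± 0.24. Ace, which encodes the angiotensin-converting enzyme, fell in both, at −0.66 ± 0.12 and −0.84 ± 0.12. Igfbp1, an insulin-repressed binding protein gene, rose by 1.36 ± 0.38 in cKOt mice and stood at 0.39 ± 0.35 in control mice (interaction 0.97 ± 0.52, adjusted p = 0.419). In the knockout contrasts the injury marker gene Havcr1 stood at −1.04 ± 0.26 in PBS and −1.45 ± 0.24 in STZ mice, both past the threshold. The tubular injury list as a whole passed camera in neither knockout contrast.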
